A study of Mus musculus with 12 samples.

How the data were processed

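RNA from mouse thymus and thymic tumors was measured on 12 Affymetrix Mouse Exon 1.0 ST arrays, 1 per pool of 3 organs, with 4 pools in each of 3 groups. Per the labels' protocols, RNA was extracted with Trizol and purified on RNeasy columns, amplified with the Ambion WT expression kit, labelled with biotin through the GeneChip WT terminal labeling kit and hybridised. The labels describe the pools of a group as biological replicates.

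The authors deposited 1 normalized intensity per transcript cluster, the array's unit for a gene, on a linear scale, for 17829 clusters on each array. The software and the normalization behind these values are not given in the sources used here. Intensities ran from 6.17 to 24310, and the median of an array lay between 186 and 210, so the arrays had been brought to a common level. The planned tests assumed log2 values. Since the intensities are linear, each was log2-transformed with no pseudocount, as foreseen for that case. Other matrices of the series hold 24 columns whose pool names match no sample label. These were not used, and the planned tests of exon usage and of a second value table were not run.

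A microarray has no read depth. The number of arrays limits the precision: the median standard error of a log2 difference was 0.100 for pre-leukemic against wild-type thymus, 0.103 for tumor against wild type and 0.128 for tumor against pre-leukemic. No detection calls or background intensities were used here, and background in the intensities makes fold changes of weakly expressed genes smaller than the change in their RNA. No value per exon was analysed, so nothing is said of splicing.

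Gene symbols came from the platform annotation, which pairs 15618 clusters with 1 symbol, 1370 with several and 841 with none. No symbol needed an update through its gene number. Clusters with several symbols or none were tested but never named. The 15618 named clusters carry 15223 distinct symbols. The builds of the annotation and of the array design were not matched here, so no coordinates are printed. Trp53, which the rule for named genes includes, has no cluster with a single symbol and was not analysed here, and a further gene of that rule is not reported here.

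Each comparison was fitted on its 8 arrays alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), as a two-sided test on log2 intensity. All 17829 clusters were tested, with no filter on low values, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The series' own criterion also asks for a posterior probability over 95%, and this was run as an alternative from limma's B with a prior share of 0.01. Every adjusted p of a single gene in the text is from this limma test. Groups are called separate where all 4 arrays of one lie above all 4 of the other, which chance gives for 2.86% of genes. Tumors differ from wild-type thymus in age and genotype as well as in disease, and from pre-leukemic thymus in age.

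Shifts of 27 gene lists, covering cell types of the thymus, stages of T-cell development and pathways, were tested with limma's camera at a preset correlation between genes of 0.01. Adjustment ran over 81 tests, 27 lists in 3 comparisons, with 1 cluster per symbol, the one with the highest mean over the 12 arrays. Camera was repeated with the correlation estimated from the data, and with fry, a rotation test of whether the genes of a list move on balance one way. The score of a list on an array is the mean log2 intensity of its members minus the mean of all named genes. Scores were compared with exact two-sided permutation tests, whose smallest possible p at 4 arrays against 4 is 0.0286. These tests were not part of the original choices. Their p were adjusted over the 27 lists of a comparison and also over all 81 tests.

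Lists, other tests, alternatives and the rule for named genes were fixed before the data were examined. Of the genes that the rule always names, Mcm4, Mcm2, Notch1 and Ikzf1 are reported here. The rule then names the 10 largest rises and the 10 largest falls among called genes whose groups were separate, leaving out predicted or provisional symbols. If fewer than 5 genes pass, it names the 10 with the smallest p. From each list it names the 2 called members with the largest rise and the 2 with the largest fall, or with none called the 2 with the smallest p. After the results were seen, this last part was limited to the 10 called lists with the smallest p in each comparison, and members of the other lists are not named under it. Drd5 is named although it has 2 clusters. Both gave the same direction.

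The gene test was checked on simulated data with the real means and spread, noise drawn independently for each gene, and 200 changed genes of 17829. For pre-leukemic against wild-type thymus it recovered 49.3% of genes changed by 0.5 on the log2 scale, 86.6% of those changed by 1 and 97.0% of those changed by 2, with 13 false calls among 17629 unchanged genes. For tumor against wild type it recovered 37.3%, 95.5% and 97.0%, with 6 false calls. For tumor against pre-leukemic it recovered 26.9%, 80.6% and 98.5%, with 11 false calls. A simulated shift of 0.3 in 1 list was recovered in all 3 comparisons, and of the 26 lists left unchanged 0, 0 and 1 were called. With noise independent between genes, this check cannot show how often camera calls unchanged lists whose genes vary together. Divisions of the real arrays other than by group called a median of 9, 9 and 10 of the 27 lists, in the same order of comparisons.

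The alternatives were a single fit of all 12 arrays, a trended robust prior, the posterior and a 1.5-fold threshold, removal of clusters below the 30th percentile, quantile normalization of the deposited values, centring on array medians, array weights, the replicate number as a block and each replicate left out in turn. Chosen after seeing the data were the interquartile range of each array as a covariate, the arrays of narrow and wide range as 2 blocks, a fit without the 4 arrays of narrowest range, and the leaving out of single arrays for the spread and the agreement of effects.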

Results

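Gene expression was measured in whole thymus and thymic tumors of female mice of the Sdl model, which carries a substitution (D573H) in 1 copy of Mcm4, a subunit of the helicase that unwinds DNA for replication. There were 4 pools of wild-type thymus and 4 of pre-leukemic thymus from heterozygotes, both taken at 21 days of age, and 4 pools of thymic tumor from moribund heterozygotes. Each pool held 3 organs and was read on 1 array. Replicates of a group correlated at 0.983 to 0.996 across genes, and no pair held identical values. The first principal component held 53.3% of the variance. It placed the tumors at 36.4 to 45.3, the wild-type thymus at -28.7 to -20.7 and the pre-leukemic thymus at -23.7 to -9.52.

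The comparison of tumor with wild-type thymus, named in the series' design, asks how far the tumors had departed from the normal organ. Tumors had far lower transcripts of cortical thymic epithelium and of fat, lower transcripts of the CD4 and CD8 double-positive stage and of interferon-induced genes, and higher transcripts of ribosome biogenesis, glycolysis and DNA replication. These are list calls with a preset correlation of 0.01 between genes, and none was kept with an estimated correlation. Prss16, the thymus-specific serine protease of cortical epithelium, fell from 11.91 ± 0.15 to 6.11 ± 0.21 (log2 intensity, mean ± SD, n = 4), a 56.0-fold decrease with a limma adjusted p of 5.47e-08. Notch1, the receptor that drives T-lineage commitment, rose by 1.18 ± 0.12 (log2 difference ± SE, n = 4 per group, limma adjusted p = 1.71e-04), and Ikzf1, which encodes the lymphoid transcription factor Ikaros, fell by 1.27 ± 0.08 (limma adjusted p = 1.55e-05). In all, 2881 clusters were higher and 2593 lower in tumors, 30.7% of those tested, of which 228 and 599 changed at least 2-fold.

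Of the 15 measured genes of cortical thymic epithelium, 15 fell, with a median of -1.94 (adjusted p = 8.84e-18, and adjusted p = 0.0849 with an estimated correlation). Besides Prss16, the largest falls were those of Tbata (-5.40 ± 0.26), a protein of thymic epithelium, and Ccl25 (-5.32 ± 0.12), the chemokine that draws progenitors into the thymus. Of 12 genes of medullary epithelium 7 fell and 0 rose (median -1.05, adjusted p = 5.65e-06, and adjusted p = 0.287 with an estimated correlation), among them Krt17 (-2.67), a keratin, and Epcam (-2.19), an epithelial adhesion molecule. All 12 measured adipocyte genes fell, by a median of -1.95 (adjusted p = 7.47e-11, and adjusted p = 0.262 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, fell by 4.66 ± 0.29 and Car3, a carbonic anhydrase abundant in fat, fell by 4.12 ± 0.55. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, fell by 4.17. Markers of other supporting cells moved less: 9 of 21 fibroblast and matrix genes fell and 1 rose (median -0.45), and 6 of 18 endothelial genes fell and 0 rose (median -0.13). Both of these lists were called at adjusted p = 1.51e-04 and 0.0139, and had an adjusted p of 0.466 and 0.581 with an estimated correlation. The macrophage and dendritic cell list was not called (6 of 21 rose and 8 fell), although Cd5l (3.22), Arg1 (3.04) and Ccl8 (2.90), genes of macrophages and of monocyte recruitment, were among the 10 largest rises. Ccl8 varied between tumors (SD 1.93) and was no longer called without wild-type replicate 1, 2 or 4 (2.81, 2.83 and 2.82) or without tumor replicate 3 (2.45).

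Genes of the double-positive thymocyte stage fell in 14 of 17 cases and rose in 1 (median -1.01, adjusted p = 6.46e-09, and adjusted p = 0.0925 with an estimated correlation). Ccr9, the receptor of Ccl25, fell by 2.89 ± 0.24, and Rag2, needed to rearrange antigen receptor genes, fell by 2.12 ± 0.17. The member that rose was Zap70, a kinase of the T-cell receptor (0.21 ± 0.06, limma adjusted p = 0.0309). Its call was lost when any wild-type array or tumor replicate 3 or 4 was left out (0.18 to 0.23), without the 4 arrays of narrowest range (adjusted p = 0.0558), with the replicate number as a block (adjusted p = 0.117) and at 1.5-fold. Of 21 genes of single-positive and mature T cells 10 fell and 4 rose (median -0.69, adjusted p = 1.91e-04, and adjusted p = 0.341 with an estimated correlation). The list of early thymic progenitors and double-negative cells was not called, with 4 of 21 members higher and 8 lower. Of 22 genes of the Notch pathway and its T-lineage targets 11 rose and 4 fell (median 0.59, adjusted p = 0.0218, and adjusted p = 0.466 with an estimated correlation). Nrarp (2.99 ± 0.36) and Dtx1 (2.82 ± 0.15), 2 regulators that Notch induces, were among the 10 largest rises under the rule for named genes. That rule takes 1 cluster per symbol, and a cluster of Drd5 that it leaves out rose by 2.88.

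Of 27 Myc targets and ribosome biogenesis genes 24 rose and 0 fell (median 0.64, adjusted p = 5.52e-12, and adjusted p = 0.287 with an estimated correlation), led by Cad (1.16), an enzyme of pyrimidine synthesis, and Polr1b (1.07), a subunit of RNA polymerase I. Glycolysis and hypoxia genes rose in 19 of 21 cases and fell in 0 (median 0.67, adjusted p = 6.46e-09, and adjusted p = 0.0850 with an estimated correlation), including Egln3 (2.11), a prolyl hydroxylase, and the glucose transporter Slc2a3 (1.23). Fbp1, an enzyme of gluconeogenesis, rose by 3.23 ± 0.31. Replication licensing and replisome genes rose in 23 of 39 cases and fell in 0 (median 0.30, adjusted p = 1.34e-06, and adjusted p = 0.435 with an estimated correlation), with Rfc5 (0.68), a clamp loader subunit, and Cdt1 (0.67), a licensing factor, as examples. Of the 10 genes of the MCM helicase list 9 rose and 0 fell (median 0.33, adjusted p = 6.28e-04, and adjusted p = 0.466 with an estimated correlation). Mcm2 rose by 0.60 ± 0.09 (limma adjusted p = 8.46e-04), and Mcm4 itself by 0.30 ± 0.08 (limma adjusted p = 0.0183), a call that was lost without wild-type replicate 2 (0.30) or 3 (0.28), with the replicate number as a block (adjusted p = 0.0568) and at 1.5-fold. DNA damage response and repair genes rose in 15 of 29 cases and fell in 0 (median 0.24, adjusted p = 1.38e-04, and adjusted p = 0.478 with an estimated correlation), including Xrcc6 (0.78), which binds DNA ends, and Brca2 (0.75), a recombination factor. Genes of mitosis and proliferation moved little: 6 of 27 rose and 1 fell, and the list was not called.

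Interferon response genes fell in 13 of 19 cases and rose in 0 (median -0.66, adjusted p = 3.84e-07, and adjusted p = 0.0925 with an estimated correlation), led by Ifit1 (-2.93) and Oasl2 (-2.32). Cxcl11, an interferon-induced chemokine outside the list, fell by 4.52 ± 0.33. B-cell genes fell in 10 of 15 cases and rose in 0 (median -0.86, adjusted p = 7.14e-06, and adjusted p = 0.343 with an estimated correlation). They included Ms4a1 (-1.95), the B-cell antigen CD20, and Cd74 (-2.16), the invariant chain that epithelial and dendritic cells also express. Neutrophil genes fell in 8 of 16 cases and rose in 0 (adjusted p = 2.41e-04, and adjusted p = 0.287 with an estimated correlation), and immediate early genes fell in 8 of 19 and rose in 3 (adjusted p = 0.0467, lost in 3 of the 8 fits that left out 1 array, and adjusted p = 0.466 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red-cell precursors, fell by 3.96 ± 0.35, but camera did not call the erythroid list (2 of 8 rose and 3 fell), which fry called (adjusted p = 0.0259). The lists of p53 targets (7 of 25 rose and 8 fell), T-ALL oncogenes (4 of 28 rose and 8 fell), T-ALL tumour suppressors (5 of 24 rose and 5 fell), glucocorticoid response (4 of 14 rose and 3 fell), NK cells (1 of 10 rose and 4 fell) and skeletal muscle (1 of 9 fell) were not called either. For the macrophage, p53, oncogene, suppressor and mitosis lists the median, the mean and the test differed in sign. The remaining named genes with the largest changes were Ccdc169 (3.63), Susd4 (3.25), the homeobox gene Emx2 (3.02) and the aldehyde dehydrogenase Aldh1b1 (2.88) among the rises, and Akr1c18 (-3.74), a steroid dehydrogenase, and Hpgd (-3.73), which degrades prostaglandins, among the falls.

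**Figure D1:**
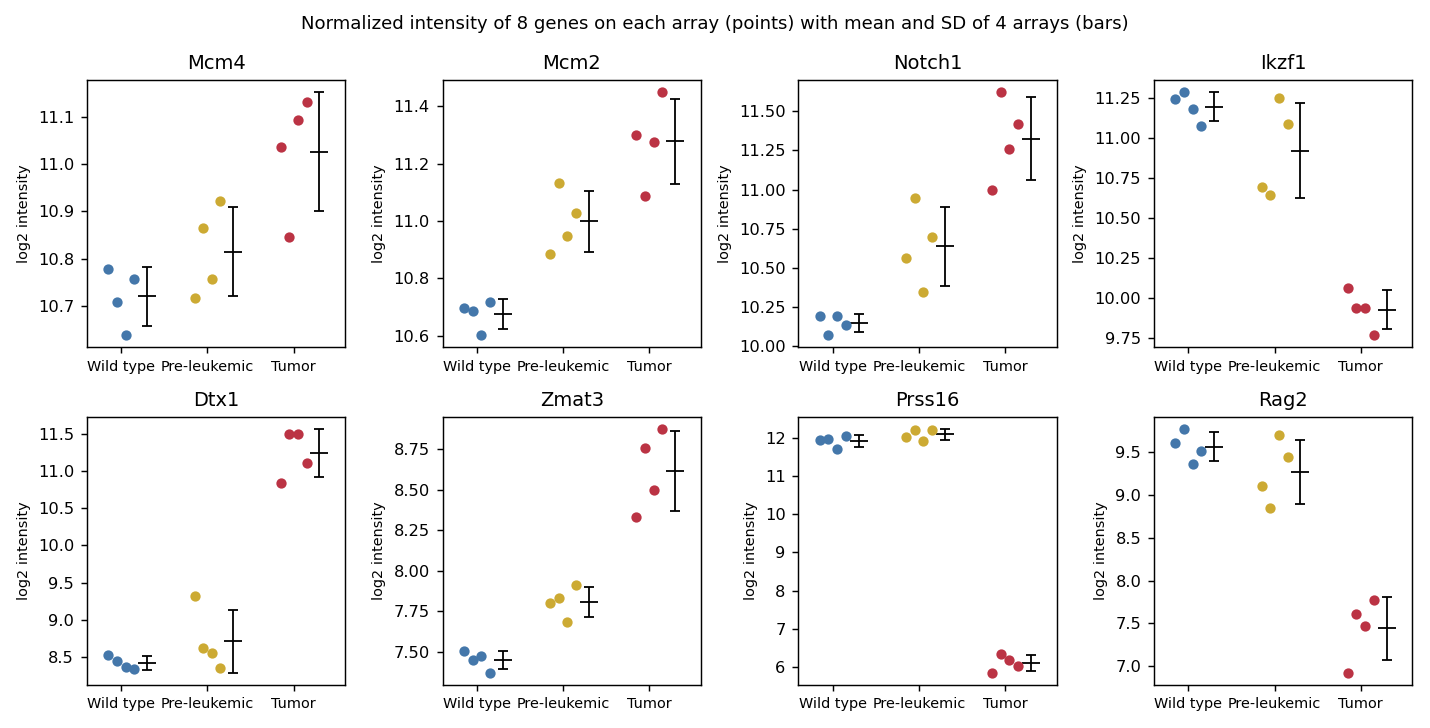
Log2 normalized intensity of 8 genes (vertical axes) in wild-type thymus, pre-leukemic thymus and thymic tumor (horizontal axes), with 1 point per array and bars for the mean and SD of 4 arrays. Prss16 averaged 11.91 in wild-type thymus and 6.11 in tumors, while Notch1 averaged 10.15 in wild-type thymus, 10.64 in pre-leukemic thymus and 11.32 in tumors.

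With a posterior over 95% from limma's B, 10 of the 41 named genes were no longer called in this comparison. They were Mcm2, Mcm4, Zap70, Rfc5, Cdt1, Brca2, Slc2a3, Ms4a1, Car3 and Ccl8. That posterior assumes a share of 0.01 changed genes, whereas limma called 30.7% of clusters. It need not match the posterior that the series' design names. Here 17 of the 27 lists were called with the preset correlation, 6 higher and 11 lower, and 0 with an estimated one. Adjusted over the list alone, member counts moved by at most 5, for DNA damage genes from 15 to 20 higher, except that the skeletal muscle list lost its 1 call. Other divisions of the 8 arrays into 4 and 4 gave up to 21 called lists, so the descriptions above rest on the counts of members called gene by gene. The scores of 18 lists, among them 15 of the 17 called, did not overlap between tumors and wild-type thymus (exact permutation p = 0.0286, adjusted p = 0.0429 over the 27 lists and 0.0681 over the 81 tests of all comparisons). The others of the 18 were the p53, erythroid and NK lists, whose scores were lower in tumors. Endothelial and fibroblast scores overlapped.

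The comparison of pre-leukemic with wild-type thymus, also named in the series' design, asks what the heterozygous Mcm4 substitution does to the thymus at 21 days. No gene was called by limma: 0 clusters passed, the smallest adjusted p was 0.573, and 1112 clusters (6.24%) had an unadjusted p under 0.05. Mcm4 itself measured 10.81 ± 0.09 in pre-leukemic and 10.72 ± 0.06 in wild-type thymus (log2, SD, n = 4), a difference of 0.09 ± 0.07 (limma adjusted p = 0.782). A probe set of this kind does not tell the substituted transcript from the wild-type one. The 10 named genes with the smallest p were all higher in pre-leukemic thymus, each with an adjusted p of 0.764. They were Mzb1 (0.89 ± 0.16), a plasma-cell and B-cell chaperone, Nr1h5 (0.80 ± 0.15), Ccr3 (0.79 ± 0.16), a chemokine receptor of eosinophils, Il12rb2 (0.41 ± 0.08), Nme4 (0.39), the linker histone H1f10 (0.36), Abcc3 (0.36), Zmat3 (0.36), a p53 target, Ppil1 (0.35) and Pold1 (0.29), the catalytic subunit of DNA polymerase delta. Notch1 (0.49 ± 0.12) and Mcm2 (0.32 ± 0.07) were also higher on all 4 pre-leukemic arrays than on all 4 wild-type arrays, at an adjusted p of 0.764. Such separation was seen for 4.43% of clusters, against 2.86% by chance. Ikzf1 measured -0.28 ± 0.14, with 10.69 and 10.65 on pre-leukemic replicates 1 and 2 and 11.25 and 11.09 on replicates 3 and 4.

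Camera with the preset correlation called 13 lists in pre-leukemic thymus, 6 higher and 7 lower, although 0 of their members were called over all genes and 0 lists held with an estimated correlation. The MCM helicase list had a median of 0.19 with 8 of 10 members positive and 6 called higher adjusted over the list alone (adjusted p = 6.27e-05, and adjusted p = 0.287 with an estimated correlation), Mcm10 (0.29) being its other named member. Replication licensing and replisome genes had a median of 0.14, with 34 of 39 positive and 11 called higher adjusted over the list alone (adjusted p = 3.58e-07, and adjusted p = 0.262 with an estimated correlation), including Gins2 (0.31), a partner of the helicase. Their score was 1.86 and 1.86 on pre-leukemic replicates 1 and 2, within the 1.81 to 1.88 of wild type, and 1.98 and 2.07 on replicates 3 and 4. Myc targets and ribosome biogenesis genes had a median of 0.13 with 22 of 27 positive and 0 called adjusted over the list alone (adjusted p = 1.60e-05, and adjusted p = 0.0850 with an estimated correlation), among them Cad (0.24) and Nop2 (0.21). These were the 3 lists that fry called, at adjusted p of 0.0208, 0.00958 and 0.00198. Cortical epithelium had a median of 0.17 with 1 member called adjusted over the list alone (adjusted p = 0.00485, and adjusted p = 0.488 with an estimated correlation), Krt18 (0.27) and Pax1 (0.22) having the smallest p. The Notch (median 0.17) and macrophage (median 0.09) lists completed the higher ones, at adjusted p = 0.0276 and 0.0417, and 0.448 and 0.488 with an estimated correlation. Their calls were lost in 3 and 4 of the 8 fits that left out 1 array, that of cortical epithelium in 2, and the number of lists called higher was between 3 and 9 in these fits.

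Lists that camera called lower in pre-leukemic thymus were led by single-positive and mature T cells, with a median of -0.24 and 2 of 21 members positive (adjusted p = 6.46e-09, and adjusted p = 0.374 with an estimated correlation). Its members with the smallest p were the interleukin 7 receptor Il7r (-0.56 ± 0.19) and Cd40lg (-0.69 ± 0.25). The score of this list was 1.45, 1.20 and 1.27 on pre-leukemic replicates 1, 2 and 4 but 1.86 on replicate 3, above the 1.63 to 1.80 of wild type. Interferon response genes had a median of -0.16 (adjusted p = 1.88e-07, and adjusted p = 0.287 with an estimated correlation), with Cxcl10 (-0.46) and Oas2 (-0.36) as examples. Double-positive genes had a median of -0.14 (adjusted p = 9.91e-06, and adjusted p = 0.448 with an estimated correlation), with Cd28 (-0.25) and Themis (-0.19), and B-cell genes one of -0.10 (adjusted p = 1.06e-04, and adjusted p = 0.262 with an estimated correlation), with Jchain (-0.66) and Cr2 (-0.20). Cr2 was weak, at log2 4.93 in wild-type and 4.73 in pre-leukemic thymus. Olfactory receptor clusters, genes that thymus is not known to use, had a median level of 4.69. The glucocorticoid (-0.12), tumour suppressor (-0.05) and medullary epithelial (-0.06) lists had adjusted p of 0.00492, 0.0179 and 0.0276, and 0.435, 0.488 and 0.488 with an estimated correlation. Their calls were lost in 2, 3 and 2 of the 8 fits that left out 1 array, and the tumour suppressor median was 0.02 without the 4 arrays of narrowest range. Their members with the smallest p included the cell-cycle inhibitors Cdkn1a (0.38) and Cdkn2b (0.25) and the deubiquitinase Cyld (-0.35). No member of these 7 lists was called adjusted over the list alone. The double-positive score was 3.35 and 3.31 on pre-leukemic replicates 1 and 2, below the 3.57 to 3.70 of wild type, and 3.71 and 3.59 on replicates 3 and 4. Replicates 1 and 2 were also the pre-leukemic arrays with the narrowest range of intensities. The other 14 lists were not called.

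**Figure D2:**
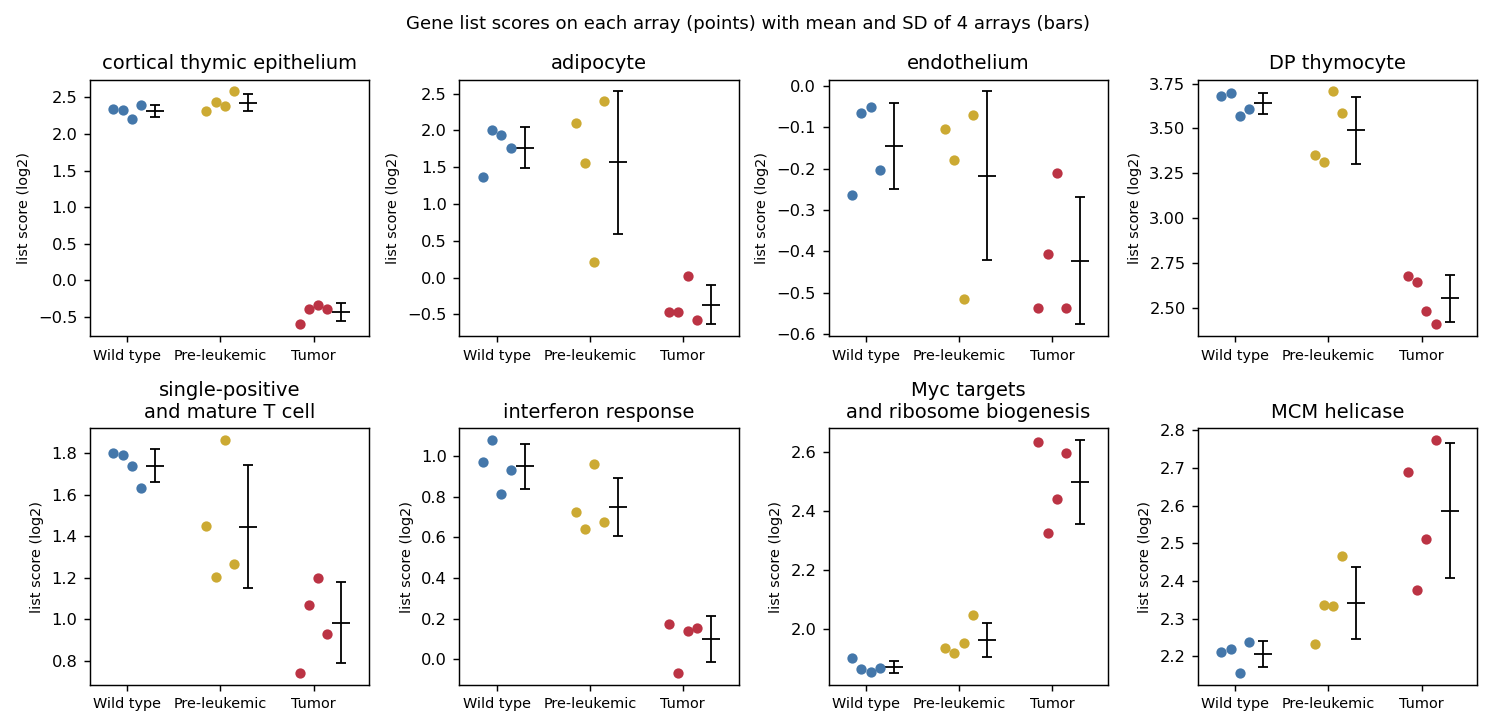
Scores of 8 gene lists (vertical axes, mean log2 intensity of the members minus that of all named genes) in wild-type thymus, pre-leukemic thymus and thymic tumor, with 1 point per array and bars for the mean and SD of 4 arrays. The cortical epithelial score lay between 2.21 and 2.58 on the 8 thymus arrays and between -0.60 and -0.33 on the 4 tumor arrays, whereas the double-positive score of pre-leukemic thymus spread from 3.31 to 3.71.

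As a limit on the pre-leukemic lists, 7 of the 35 divisions of the 8 arrays into 4 and 4 called as many lists as the real one, with up to 18. Without pre-leukemic replicate 3, limma called 1 gene, Fcna (0.80 ± 0.06, adjusted p = 0.0339, against 0.62 ± 0.16 with all arrays), a ficolin of macrophages named after its values were seen.

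Tumor was compared with pre-leukemic thymus as well, a comparison that the 3 groups imply and that keeps the genotype the same. Tumors again had far lower transcripts of cortical epithelium and fat and higher ones of ribosome biogenesis and glycolysis, list calls of which again none was kept with an estimated correlation. Prss16 fell by 5.98 ± 0.12 (63.0-fold, limma adjusted p = 2.90e-08), Tbata by 5.47 ± 0.25 and Ccl25 by 5.31 ± 0.13. Notch1 rose by 0.69 ± 0.16 (limma adjusted p = 0.0209) and Ikzf1 fell by 1.00 ± 0.15 (limma adjusted p = 0.00243). The differences of Mcm2 (0.28 ± 0.10, adjusted p = 0.102) and Mcm4 (0.21 ± 0.10, adjusted p = 0.185) were not called by limma, although Mcm2 was called with all 12 arrays in 1 fit (adjusted p = 0.0312) and with array weights (0.35, adjusted p = 0.0308). In all, 1380 clusters were higher and 1475 lower, 16.0% of those tested, of which 182 and 444 changed at least 2-fold. The counts of list members below are to be read against this share. With each array centred on its median, 57.2% of the called clusters were higher in tumors, against 48.3% as deposited.

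All 15 cortical epithelial genes fell (median -2.18, adjusted p = 3.87e-24, and adjusted p = 0.0596 with an estimated correlation), among the largest Krt18 (-3.93), a keratin, and Psmb11 (-3.72), the proteasome subunit of cortical epithelium. Of 12 adipocyte genes 11 fell (median -1.73, adjusted p = 1.88e-07, and adjusted p = 0.402 with an estimated correlation), with Ucp1 at -4.70 ± 0.64 and Car3 at -3.57 ± 0.76. Double-positive genes fell in 13 of 17 cases and rose in 0 (median -0.90, adjusted p = 4.96e-09, and adjusted p = 0.181 with an estimated correlation), including Ccr9 (-2.70) and Rag2 (-1.83). Medullary epithelial genes fell in 7 of 12 cases (adjusted p = 1.04e-06, and adjusted p = 0.287 with an estimated correlation), including Krt17 (-2.58) and Epcam (-2.01). Interferon genes fell in 10 of 19 cases (adjusted p = 3.74e-06, and adjusted p = 0.208 with an estimated correlation), with Ifit1 at -2.54 and Oasl2 at -2.26. B-cell genes fell in 7 of 15 cases (adjusted p = 2.75e-05, and adjusted p = 0.287 with an estimated correlation), with Cd74 at -2.02 and Ms4a1 at -1.47. Neutrophil genes fell in 6 of 16 cases (adjusted p = 2.76e-05, and adjusted p = 0.419 with an estimated correlation), led by the granule protein Ngp (-2.94 ± 0.40) and the calprotectin subunit S100a8 (-2.43 ± 0.35).

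Myc targets and ribosome biogenesis genes rose in 21 of 27 cases (median 0.51, adjusted p = 3.19e-14, and adjusted p = 0.205 with an estimated correlation), including Cad (0.92) and Polr1b (0.90). Glycolysis and hypoxia genes rose in 17 of 21 cases (median 0.64, adjusted p = 1.54e-11, and adjusted p = 0.0850 with an estimated correlation), including Egln3 (2.14) and Slc2a3 (1.08). Replication licensing genes rose in 6 of 39 cases (median 0.17, adjusted p = 1.42e-04, and adjusted p = 0.466 with an estimated correlation), including Wdhd1 (0.46) and Prim2 (0.46), a primase subunit. The Notch list had 11 of 22 members higher and 3 lower (adjusted p = 0.0174, and adjusted p = 0.448 with an estimated correlation), with Nrarp (2.69 ± 0.39) and Dtx1 (2.53 ± 0.22) again among the largest rises. Also among the 10 largest rises were Ccdc169 (3.39), Fbp1 (3.19), Arg1 (3.01), Saa3 (2.96), an acute-phase protein, Ccl8 (2.90 ± 0.78), Susd4 (2.83), the dopamine receptor Drd5 (2.70) and Aldh1b1 (2.35). Among the 10 largest falls were also Cxcl11 (-4.06), Alas2 (-3.80), Hpgd (-3.79) and Cox8b (-3.78). The other called lists were MCM helicase (0 of 10 members called), DNA damage (7 of 29 higher), single-positive T cells (4 of 21 higher and 6 lower), erythroid (1 of 8 higher and 4 lower), endothelium (3 of 18 lower), fibroblast (1 of 21 higher and 3 lower) and skeletal muscle (0 of 9 called), none of them with an estimated correlation, where the smallest of their adjusted p was 0.448. The endothelial, skeletal muscle and fibroblast lists lost their calls in 6, 5 and 2 of the 8 fits that left out 1 array, and the single-positive list in 1. The other 9 lists were not called. The scores of 14 lists, 12 of them called, did not overlap (exact permutation p = 0.0286, adjusted p = 0.0551 over the 27 lists and 0.0681 over the 81 tests). The others of the 14 were the p53 and NK lists, and fry called the p53 list (adjusted p = 0.00358). Adjusted over the list alone, 25 Myc targets were higher, 13 interferon genes were lower, 4 single-positive genes were higher and 9 lower, and 6 p53 targets were higher and 8 lower.

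Without the 4 arrays of narrowest range, which are 2 of the 4 in each group, 400 clusters were higher and 453 lower in tumors than in pre-leukemic thymus. Notch1 (0.69, limma adjusted p = 0.131) and Ccl8 (3.07, limma adjusted p = 0.180) were then among 15 of the 41 named genes no longer called. With all arrays kept, and their range as a covariate or as 2 blocks, none of the 41 named genes changed its call. With limma's posterior over 95%, at the prior share of 0.01, the calls of 15 named genes were lost. They were those of Notch1, Ikzf1, Nrarp, Polr1b, Wdhd1, Prim2, Slc2a3, Saa3, Ccl8, Ms4a1, S100a8, Ngp, Car3, Cox8b and Ucp1. Notch1 also lost its call without pre-leukemic replicate 1 (0.66) or tumor replicate 4 (0.66), and Ccl8 without any pre-leukemic array or tumor replicate 3 or 4 (2.25 to 2.97), while the count of higher clusters was 752 without pre-leukemic replicate 1 and 814 without tumor replicate 4.

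Log2 differences of pre-leukemic and of tumor arrays against wild type correlated at r = 0.474 across clusters, which are not independent replicates, with a covariance of 0.0347 and the same sign for 72.0% of clusters. The same wild-type arrays enter both. Unchanged groups were simulated from resampled deviations of each group, wild type included, with signs flipped at random. They gave a mean r of 0.342 (range -0.288 to 0.819 in 100 draws) and a mean covariance of 0.00750 (-0.00828 to 0.0476), with the same sign for 59.5% of clusters (32.7% to 80.3%). All 3 observed values lie within the simulated ranges. As these draws hold no tumor effect, their r is not on the scale of the observed r, and setting one against the other decides nothing. With the wild-type arrays split so that each comparison had 2 of its own, r averaged 0.313 (0.255 to 0.373 over 6 splits) and the covariance 0.0270. As 0 genes were called in pre-leukemic thymus, no overlap of calls could be counted. Leaving out wild-type replicate 2, pre-leukemic replicate 2 or pre-leukemic replicate 3 gave r = 0.427, 0.399 and 0.375.

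The spread between replicates differed between groups. The median SD of a gene was 0.0929 in wild-type thymus, 0.174 in pre-leukemic thymus and 0.178 in tumors. The ratio to wild type was 1.87 for pre-leukemic thymus and 1.91 for tumors, each with an exact permutation p of 0.0286, the smallest that 4 arrays against 4 allow, and that of tumors to pre-leukemic thymus was 1.02 (exact permutation p = 0.886). Without wild-type replicate 1 or pre-leukemic replicate 3 the pre-leukemic ratio had an exact p of 0.0571 (1.78 and 1.64). The interquartile range of log2 intensity was between 2.56 and 2.76 on pre-leukemic replicates 1 and 2 and tumor replicates 2 and 3, and between 2.84 and 3.17 on the other 8 arrays. Without those 4 arrays the ratios to wild type were 1.18 (exact permutation p = 0.467) and 0.913 (exact permutation p = 0.800). Only 15 divisions of the arrays were then possible, too few for an exact p under 0.05. With fewer arrays than wild type, these groups also have a lower median SD at the same spread. The 2 ratios therefore do not show that the excess spread was gone.

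**Figure D3:**
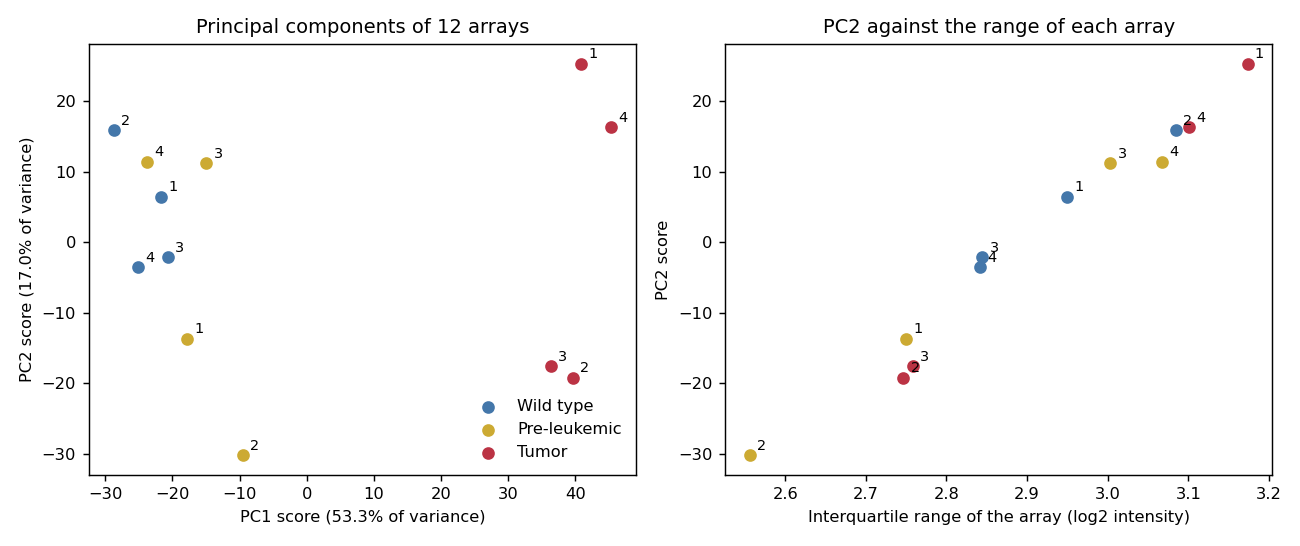
Left, scores of the 12 arrays on the first (horizontal, 53.3% of variance) and second (vertical, 17.0%) principal components, coloured by group and numbered by replicate. Right, the second component against the interquartile range of log2 intensity of each array, on which pre-leukemic replicates 1 and 2 and tumor replicates 2 and 3 have the narrowest ranges, 2.56 to 2.76.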

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

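The tests of the array range, of the pre-leukemic list shifts, of the stromal genes, of divisions of the arrays by number of genes and of divisions by list scores were chosen after the results they bear on had been seen, whereas the divisions by number of lists called and the rule for single outlying arrays were set beforehand.

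Single arrays stood apart from the other 3 of their group in 16 of the 309 cases examined (5.18%), about the share that chance gives. A case is a named gene, a list score, or the median or range of the arrays, within 1 group. The share given here is the gap to the nearest array over the whole range of the group. In wild-type thymus these were Ccl8 on replicate 3 (log2 6.55 against a mean of 5.63 on the others, share 0.943), Tbata on replicate 3 (12.12 against 12.39, share 0.907), Cr2 on replicate 2 (5.12 against 4.86, share 0.957), Cyld on replicate 4 (8.83 against 8.995, share 0.973) and Fbp1 on replicate 4 (7.34 against 5.98, share 0.862). In pre-leukemic thymus they were Ccl25 on replicate 1 (12.97 against 13.13, share 0.840), Egln3 on replicate 2 (8.77 against 9.03, share 0.929), Epcam on replicate 3 (9.22 against 8.74, share 0.834) and Nop2 on replicate 3 (8.92 against 9.11, share 0.835). In tumors they were Abcc3 on replicate 3 (7.45 against 7.28, share 0.902), Cd28 on replicate 4 (9.34 against 10.09, share 0.859), Drd5 on replicate 1 (8.002 against 8.99, share 0.841) and Emx2 on replicate 1 (7.62 against 9.01, share 0.962). Among list scores they were the early thymic progenitor score of tumor replicate 3 (0.17 against -0.02, share 0.939), the interferon score of tumor replicate 2 (-0.07 against 0.15, share 0.852) and the skeletal muscle score of tumor replicate 1 (0.61 against -0.52, share 0.878).

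The second principal component followed the interquartile range of the 12 arrays (Pearson r = 0.987, permutation p = 1e-05, the smallest that the resamples can give; Spearman rho = 0.993, permutation p = 2e-05; r = 0.976 without the 2 arrays farthest from the median range), and 2 pre-leukemic and 2 tumor arrays lay at its narrow end. A uniform compression of the intensity scale is argued against as the whole cause, because quantile normalization left the axis with 26.7% of the variance within groups, from 37.1%, and array scores that correlated at 0.996 with those before. Non-specific signal on some arrays stays open and is in line with the 787 olfactory receptor clusters, genes that thymus is not known to use (median log2 level 4.69), whose difference between narrow and other arrays of the same groups was 0.0488 after quantile normalization, above the -0.0127 to 0.0254 of 1000 level-matched draws. That measure replaced an earlier one that also lay outside its draws. RNA quality and hybridisation batch stay open, as no label gives them, and no biological explanation was tested.

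The shifts of 13 lists in pre-leukemic thymus are not beyond what divisions of the arrays can give, since 7 of 35 divisions called as many and the highest other called 18. The range of the arrays stays open: with it as a covariate 12 of the 13 lists were still called in the same direction, among 14 in all, but 7 of 35 divisions then called as many, the highest other 17, and only 9 of the 13 were kept with 2 blocks of range or without the narrow arrays. The Mcm4 genotype stays open: the smallest exact permutation p of a list score, adjusted over the lists, was 0.386. Litter or a day of preparation would part the groups in the same way and was not tested. List scores without overlap were 2 in the real division, reached by 8 of 35, with 5 in the highest other. For genes, 0 were called, so that 35 of 35 divisions had to call as many, the highest other calling 0, and this count decides nothing. At an unadjusted p under 0.05 there were 1112 clusters, which 10 of 35 divisions reached, and the highest other, at 4045, set the 4 arrays of widest range against the 4 of narrowest, which points to a structure of the samples.

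In tumors the fall of cortical epithelial genes and of fat genes has several possible explanations. An even loss of every cell type other than the tumor cells is argued against, because cortical epithelial genes fell further than endothelial genes, by a difference of medians of -1.81 (95% interval -3.40 to -1.13 with genes resampled). Part of that can be a matter of level, as background shrinks the falls of weaker genes. The endothelial score was -0.514 to -0.0515 on the 8 thymus arrays and the cortical score 2.21 to 2.58. Fibroblast and matrix genes scored 0.927 to 2.10 there, and the difference from them was -1.49 (-3.14 to -0.848). The differences from medullary epithelial genes (-0.889, -3.02 to 0.315) and from fat genes (0.0112, -1.78 to 0.770) had intervals that include 0. Resampling genes does not measure variation between pools. Fat taken with the thymus is consistent with the spread of the fat score on the 8 thymus arrays, whose SD within groups was 7.19 times that of the cortical score, or 3.31 times without pre-leukemic replicate 3, which scored 0.214 against 1.37 to 2.40 on the others. Whether the epithelium was lost, diluted by tumor cells more than the endothelium, or changed with age stays open, since tumor and age go together in these groups.

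For tumor against wild-type thymus, 1 of 35 divisions of the arrays, the real one, gave 5474 genes and the highest other gave 0. This argues against chance division for the number of genes, although 1 of 35 is the smallest share that the test can give. Divisions that mix the groups also carry the group difference in their spread, which lowers their number of calls. For the lists that camera called, 17, 6 of 35 divisions called as many and the highest other called 21, so chance division stays open there. Scores of 18 lists did not overlap in the real division, the only 1 of 35 to reach that, against 2 in the highest other. That share is again the smallest possible. It argues against chance division for the number of scores without overlap, but not for any single list. No single list score had an adjusted p under 0.05 over all 81 tests, where the smallest was 0.0681. For tumor against pre-leukemic thymus 1 of 35 divisions gave 2855 genes, again the real one, but the highest other gave 2361. That division set pre-leukemic replicates 1 and 2 and tumor replicates 2 and 3, the arrays of narrow range, against the rest, and so points to a structure of the samples besides the groups. With narrow and other arrays as 2 blocks, 2215 genes were higher and 2062 lower in tumors. Adjusted within this comparison, 19 lists were called, 2 of 35 divisions called as many, and the highest other called 21. Scores of 14 lists did not overlap in the real division, the only 1 of 35 to reach that, against 3 in the highest other.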

How the results depend on the processing

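The array range as a covariate or as 2 blocks, the fits without the 4 arrays of narrowest range, and the leaving out of arrays for spread and agreement were chosen after seeing the data, and all other alternatives before. The cause was not tested for the changes below, except that stricter thresholds and fewer arrays call fewer genes by construction. For tumor against wild type (2881 higher, 2593 lower) the counts were 351 and 535 with a posterior over 95%, 850 and 1292 at 1.5-fold, and 5033 and 3280 with the range as a covariate. For tumor against pre-leukemic (1380 and 1475) they were 112 and 252, 556 and 983, and 2337 and 1924 in the same order, 2194 and 2096 with all 12 arrays in 1 fit, 2215 and 2062 with 2 blocks, and 400 and 453 without the narrow arrays. Pre-leukemic against wild type stayed at 0 and 0 under every alternative but 1, the fit without pre-leukemic replicate 3, which called 1 gene, and 4140 clusters had an unadjusted p under 0.05 with array weights. With an estimated correlation 0 lists were higher and 0 lower in each comparison, and with fry 3 were higher and 0 lower in pre-leukemic thymus. No named gene changed direction. The ratio of spreads was 1.18 for pre-leukemic and 0.913 for tumor against wild type without the narrow arrays, where the first group keeps fewer arrays and its median SD is lowered by that. For tumor against pre-leukemic it was 0.777 without them and 0.977 after quantile normalization. The agreement of effects was r = 0.313 with the wild-type arrays split and 0.394 without the narrow arrays.

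The replicate number as a block gave 900 higher and 1163 lower genes for tumor against pre-leukemic, 2095 and 2115 for tumor against wild type, and 0 and 0 for pre-leukemic against wild type. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.554 to -0.0387, -0.396 to 0.148 and -0.406 to 0.423 in pre-leukemic and wild-type, tumor and wild-type, and tumor and pre-leukemic arrays, and 0, 1 and 3 of the 8 arrays correlated best with their own number.

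With 1 array left out, genes higher and lower ranged from 0 to 1 and 0 to 0 for pre-leukemic against wild type, 2091 to 2954 and 2025 to 2591 for tumor against wild type, and 752 to 1284 and 976 to 1484 for tumor against pre-leukemic. Lists higher and lower ranged from 3 to 9 and 6 to 9, 6 to 6 and 10 to 13, and 6 to 6 and 9 to 14. The ratios of spread ranged from 1.61 to 2.22, 1.75 to 2.27 and 0.939 to 1.18, and the agreement from 0.375 to 0.513.

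List medians that changed sign belonged to lists not called at first, tumour suppressors in pre-leukemic thymus excepted. With low values removed these were p53 targets (-0.0882) and NK cells (0.0418) in tumor against wild type and macrophages (0.00356) in tumor against pre-leukemic. With the range as a covariate they were fibroblasts in pre-leukemic thymus (-0.0286) and T-ALL oncogenes in tumor against pre-leukemic (0.0305). Without the narrow arrays, and with 2 blocks, they were early progenitors (-0.0190), T-ALL oncogenes (-0.0292), tumour suppressors (0.0170) and immediate early genes (-0.0482) in pre-leukemic thymus, and p53 targets (-0.0500) and T-ALL oncogenes (-0.0484) in tumor against wild type. Macrophages in tumor against pre-leukemic (0.0399) did so without the narrow arrays. With 1 array left out, medians in pre-leukemic thymus ran from -0.0170 to 0.0428 for mitosis, -0.0161 to 0.0398 for p53 targets, -0.0359 to 0.116 for immediate early genes, -0.106 to 0.0569 for endothelium, -0.207 to 0.262 for fibroblasts, -0.413 to 0.266 for adipocytes, -0.0184 to 0.0465 for NK cells and -0.116 to 0.503 for muscle. They ran from -0.0295 to 0.307 for macrophages in tumor against wild type, and in tumor against pre-leukemic from -0.0768 to 0.0208 for mitosis, -0.0809 to 0.0400 for T-ALL oncogenes and -0.182 to 0.105 for macrophages. A list called in neither of 2 fits was compared by the sign of its median, a rule set after a first version had been seen. Tests of exon usage and of a second value table were not run. Signal over background was not used here, so weak genes have the least certain folds.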

Other observations

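The genes in the next 2 paragraphs were chosen after their values were seen, while the bound of the test in the last paragraph was written beforehand.

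In tumors against wild-type thymus 4 genes encoding MHC class II chains or their chaperone fell, which says nothing of the class as a whole because no list of it was tested. They were H2-Ea (-2.06 ± 0.19), H2-Aa (-1.89 ± 0.19), H2-Ab1 (-1.70 ± 0.31) and H2-DMa (-0.88 ± 0.13; log2 difference ± SE, limma adjusted p from 7.50e-05 to 0.00300). Notch3 (1.25) and the Notch targets Heyl (2.35), Hes1 (2.03), Il2ra (1.72) and Myc (1.28) rose, while Ptcra, the pre-T-cell receptor chain that Notch also induces, measured 0.66 and was not called (limma adjusted p = 0.0674). Cytokine receptors went both ways. Il12rb2 (2.08) and Il9r (1.51) rose, Il4ra (-1.55) and Il18r1 (-1.24) fell, and Il7r rose by 0.42 although its groups were not separate.

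Among transporters of amino acids, the leucine carrier Slc7a5 (1.17) and its partner Slc3a2 (0.57) rose in tumors against wild-type thymus, the cystine carrier Slc7a11 fell (-1.94 ± 0.48), and the glutamine carrier Slc1a5 measured -0.06 and was not called. Granzyme A (Gzma) rose by 1.58 ± 0.07, while Klrd1, a receptor of cytotoxic cells, fell by 1.57 ± 0.13. The p53 target Zmat3 rose by 1.16 ± 0.12, whereas Cdkn1a, another, measured 0.23 ± 0.16 and was not called. Of 41 ribosomal protein genes 18 were higher and 0 lower in tumors against wild type (median 0.217), 5 were higher and 0 lower against pre-leukemic thymus, and 0 were called in pre-leukemic thymus.

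A hypothesis is that some pre-leukemic pools already held tumor cells at 21 days. The 10 named genes with the largest rise in tumors against wild-type thymus were examined for lying above all 4 wild-type arrays, with a bound of 8 of 10 set beforehand. The counts were 7, 7, 2 and 2 on pre-leukemic replicates 1 to 4, and the highest, 7, missed the bound, which under the rule written beforehand speaks against tumor cells. That the hypothesis is nevertheless left open was decided after the count was seen, because its 95% exact binomial interval of 34.8% to 93.3% includes 8 of 10. That interval takes the 10 genes of 1 array as independent trials, which they are not, and is weak ground for setting the rule aside. Nor does the count measure tumor cells alone, since Cd5l, Arg1 and Ccl8 among the 10 are genes of macrophages and monocyte recruitment. Cd5l stood at 7.04, 7.47 and 7.44 on replicates 1, 2 and 4, against at most 6.27 in wild type. After quantile normalization the counts were 7, 6, 2 and 2. On the linear scale, the rise of these genes above the wild-type mean was set against their mean rise in tumors. Its median share was 8.57% and 4.42% on replicates 1 and 2, and -0.0687% and -0.446% on replicates 3 and 4. A wild-type array lay above the other 3 for 1 to 5 of the genes. Since replicates 1 and 2 are also the pre-leukemic arrays of narrow range, tumor cells cannot be told apart from a property of those arrays.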
